A study of Mus musculus with 2 samples.

How the data were processed

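RNA of the mouse B-cell lymphoma line CH12.LX was measured in 2 libraries, which the labels number as biological replicates 1 and 2 of separate biosamples. They form 1 group of 2, so no comparison between conditions exists, and the replicate numbers were taken from the labels. Per the labels, ERCC spike-in RNAs were added and RNA longer than 200 nt was used. The labels name the assay as total RNA sequencing while their description says poly(A)+, and which of these holds was not settled here. Whether libraries kept the strand, whether reads were paired, and the aligner, the quantification tool and their versions are not given in the sources used here.

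For each library the authors deposited a table of genes and a table of transcripts, made from alignments to mm10 with GENCODE annotation M4 and spike-in sequences. Expected counts are, per the file headers, estimated reads or fragments per feature that divide shared reads between features, and they are not normalized. TPM values, deposited by the authors, are relative transcript abundances scaled to the same total over all features including the spike-ins, so every value depends on the rest of the library. FPKM values were deposited as well, counts scaled by feature length and library size, and served only for 1 alternative of the correlation between replicates. The transcript tables hold an isoform percent deposited by the authors, the share of a gene's TPM on each transcript. Posterior mean counts, their SD and posterior mean TPM, also deposited, were used as alternatives and to mark genes with uncertain shared reads. The deposited credibility bounds of TPM and FPKM were not used, and the text files that accompany each library hold no measurements.

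The gene tables hold 69691 features: 43346 genes, 26248 features named only by a number, 96 ERCC spike-ins and phiX174. The numbered features had 0 counts in both libraries. Gene symbols, types and coordinates came from GENCODE annotation M21 on GRCm38, the assembly also named mm10, by matching the identifier without its version. A symbol was found for 42462 genes, and the 884 without one held 0.154% ± 0.00363 of the counts. Of the 11661 genes used for differences, 99.5% had a GC content and length from the reference.

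Gene lists, 38 in all, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The lists cover B-cell stages, other cell types, immunoglobulin genes, signalling, antigen presentation, metabolism, stress, proliferation and RNA classes. The named genes are the 10 highest by mean TPM, of each list the highest, the lowest and others needed to describe it (not all are printed), the 10 largest differences between replicates in each direction at a mean of 100 or more counts, the immunoglobulin constant genes, the sex-linked genes and a fixed set for isoforms. Mtap, Klhl9, Gm12609, the X-linked copies, the variable segments, the isoforms of Igha and the genes of the closing observations were chosen after their values were seen. Iglc1 and Iglc3 had no feature under that symbol, so the light-chain list rests on 2 genes.

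A gene counted as expressed at 1 TPM or more in both replicates. Differences are replicate 2 minus replicate 1 of log2(TPM + 0.5) over genes with a mean expected count of 20 or more, and the pseudocount understates differences of low genes. The median difference of each list with at least 3 such genes was placed among 10000 random lists of the same size drawn from 20 bins of mean expected count with a fixed seed, and lists outside the central 95% (percentiles 2.5 to 97.5) were called. With 1 library on each side this describes the libraries, and no p-value across genes was computed. Counting error was tested per gene with a binomial test and Benjamini-Hochberg adjustment at 0.05 on genes whose counts were whole in both libraries. The limit of 3 counts behind a count of 0 covers counting error only, because reads without molecular identifiers are not independent molecules. The Wilson interval is over genes of this pair of libraries, which are not independent draws, and covers no spread between replicates.

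The list procedure was tested on simulated data for the comparison of replicate 2 with replicate 1 over 11661 genes, with 25 lists of 12 genes per shift and 2000 random lists. At a noise of 0.10 log2 units per replicate, all 25 lists shifted by -0.3, by 0.3 and by 0.6 were called, and 2 of 25 unshifted lists. At a noise of 0.22 log2 units, 23 of 25 shifted by -0.3, 16 of 25 shifted by 0.3 and 25 of 25 shifted by 0.6 were called, and again 2 of 25 unshifted lists. The lower noise was set from the data after a first run with a larger assumed noise had missed the recovery aimed for. The simulated noise was independent between genes and held no trend with GC content, so variation that genes of a list share is not covered.

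Alternatives were edgeR's TMM factors on rounded expected counts, median-of-ratios size factors, scaling to the ERCC spike-ins (these 3 use expected counts without effective lengths, and each applies 1 factor per library, so that lists differ among them only by that factor and through the pseudocount), posterior mean TPM, other pseudocounts (0.1 and 2), other count minimums, other TPM thresholds (0.5 and 5), shares by TPM in place of counts, and each replicate alone. Removal of features with an effective length under 100 nt, the correction for GC content and length in 20 bins each, a spike-in minimum of 20 counts, a robust SD of the spike-ins and median-of-ratios factors for the lists were added after the data were seen. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, were used.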

Results

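RNA sequencing was used to measure gene expression in CH12.LX, an established mouse B-cell lymphoma line that the labels call the counterpart of the human B-lymphoblastoid line GM12878. The line comes from strain B10.H-2aH-4bp/Wts. The 2 libraries are biological replicates from separate biosamples and form 1 group, and the labels name no treatment or second cell type. The libraries held 24469094 and 23586580 expected counts. The comparisons that this design allows are between gene groups within the line and between the 2 replicates. Levels are given as mean ± SD in TPM, relative transcript abundance scaled to the same total in each library, over the 2 replicates (n = 2), and coordinates are those of GRCm38, the assembly also named mm10.

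CH12.LX expressed 10998 of 43346 annotated genes at 1 TPM or more in both replicates, of which 9862 were protein-coding, 275 long non-coding and 735 pseudogenes. The highest protein-coding nuclear genes were Eef1a1, a translation elongation factor, at 16346 ± 94.3 TPM, Ppia, a prolyl isomerase, at 7388 ± 224 TPM, Npm1, a nucleolar chaperone, at 6302 ± 166 TPM, Hspa8, a constitutive heat-shock chaperone, at 5718 ± 353 TPM, and Tmsb4x, an actin-binding peptide, at 5597 ± 608 TPM. The mitochondrial gene mt-Co1, a cytochrome oxidase subunit, reached 12457 ± 1135 TPM. The top 10 also held 3 pseudogenes, Gm28437 at 8944 ± 134 TPM, Gm28438 at 8856 ± 2091 TPM and Rpl27-ps3 at 6669 ± 278 TPM, whose levels are uncertain because such copies can share reads with their parent genes. The first place of mt-Atp8, at 78258 ± 17860.5 TPM, rested on its short length: it held only 6068 and 5824 counts, and its deposited effective length was 4.42 and 3.2 nt. All 14 reference genes reached 1 TPM in both replicates, from Polr2a at 9.62 ± 2.46 TPM to Eef1a1.

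Genes of mature B cells were expressed broadly, and genes of other blood and stromal cells were mostly at or near 0. Across the 6 lists for mature B-lineage cells, 82 of 89 genes reached 1 TPM in both replicates, with a median of 35.3 TPM, against 12 of 74 genes and a median of 0.0750 TPM across the 6 lists for other cell types. Among surface genes, 17 of 18 passed: Cd24a, a small glycosylated surface antigen, stood at 2099.5 ± 32.9 TPM and Ms4a1, which encodes CD20, at 524 ± 43.5 TPM, while the complement receptor gene Cr2 stood at 0.430 ± 0.0566 TPM. The signalling chains of the B-cell receptor were uneven, with Cd79b at 507 ± 30.9 TPM and Cd79a at 37.7 ± 2.99 TPM, a ratio of 13.5 ± 0.250.

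Of the B-cell transcription factors, 20 of 22 reached 1 TPM. Spib, an ETS factor, was highest at 119 ± 17.1 TPM, with the B-cell coactivator Pou2af1 at 119 ± 0.898 TPM and Irf4, which acts in B-cell activation and plasma-cell differentiation, at 102 ± 11.8 TPM. Pax5, the B-lineage commitment factor, was at 8.43 ± 0.933 TPM, Foxo1 at 0.495 ± 0.163 TPM and Bach2, a repressor of plasma-cell differentiation, at 0.0150 ± 0.00707 TPM. All 18 genes of B-cell receptor signalling passed, from Dok3 at 6.50 ± 0.0212 TPM to Cd81 at 262 ± 11.3 TPM, and the kinases Syk and Btk stood at 85.9 ± 5.32 and 27.3 ± 3.06 TPM.

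Genes of several B-cell stages were present together. Of 12 germinal-centre genes, 9 reached 1 TPM, led by the G-protein regulator Rgs13 at 1052 ± 132 TPM, while Bcl6, the germinal-centre repressor, stood at 0.185 ± 0.0354 TPM. Of 12 plasma-cell genes, 11 passed: Mzb1 and Jchain, which act in antibody secretion and polymer assembly, reached 1325 ± 163 and 975 ± 49.3 TPM, whereas Prdm1, the plasma-cell master regulator, was at 3.51 ± 0.156 TPM and Tnfrsf17 at 0.285 ± 0.0495 TPM. All 7 B-1 cell genes passed, with Zbtb32 at 125 ± 9.77 TPM, Cd5, a surface marker of B-1a cells, at 14.3 ± 1.52 TPM and Spn lowest at 1.96 ± 0.106 TPM. Of 12 pro-B and pre-B genes, 1 passed, the receptor kinase gene Flt3 at 2.5 ± 0.0919 TPM. The recombinase gene Rag1 was at 0.010 ± 0 TPM, and Rag2 had 0 counts.

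Among the lists for other cell types, 3 of 17 T-cell, 0 of 10 NK and cytotoxic, 2 of 14 myeloid, 3 of 8 dendritic, 3 of 12 erythroid and megakaryocyte, and 1 of 13 stromal, endothelial and epithelial genes reached 1 TPM in both replicates. The highest were the myeloid lysosomal gene Cd68 at 93.6 ± 0.233 TPM, the helix-loop-helix factor Tcf4 at 60.5 ± 2.99 TPM, the kinase gene Lck at 51.6 ± 3.15 TPM, Batf3 at 29.8 ± 6.43 TPM and Pecam1 at 14.8 ± 0.983 TPM. Lower genes of these lists that also passed were Cd2 at 8.46 ± 1.65 TPM, the macrophage surface gene Adgre1 at 6.70 ± 0.552 TPM, the dendritic-cell factor Zbtb46 at 4.94 ± 0.255 TPM and Cd3g at 1.16 ± 0.226 TPM, the last with 22 and 16 counts. Of the members that did not pass, Cd3e, Thy1, S100a8 and Cd14 had 0 counts in both libraries, which for Cd3e allows up to 0.118 and 0.123 TPM (3 counts), and the macrophage lysozyme Lyz2 stood at 0.120 ± 0.0283 TPM, with Itgax, a dendritic-cell integrin gene, at 0.230 ± 0.0424 TPM and the endothelial cadherin gene Cdh5 at 0.260 ± 0.141 TPM. The NK and cytotoxic genes were highest for Prf1, which encodes perforin, at 0.230 ± 0.0141 TPM. Hbb-bt was the highest erythroid gene at 4.47 ± 0.127 TPM, and the similar gene pair Hba-a1 and Hba-a2, at 3.60 ± 0.615 and 2.30 ± 0.0990 TPM, can divide shared reads.

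**Figure D1:**
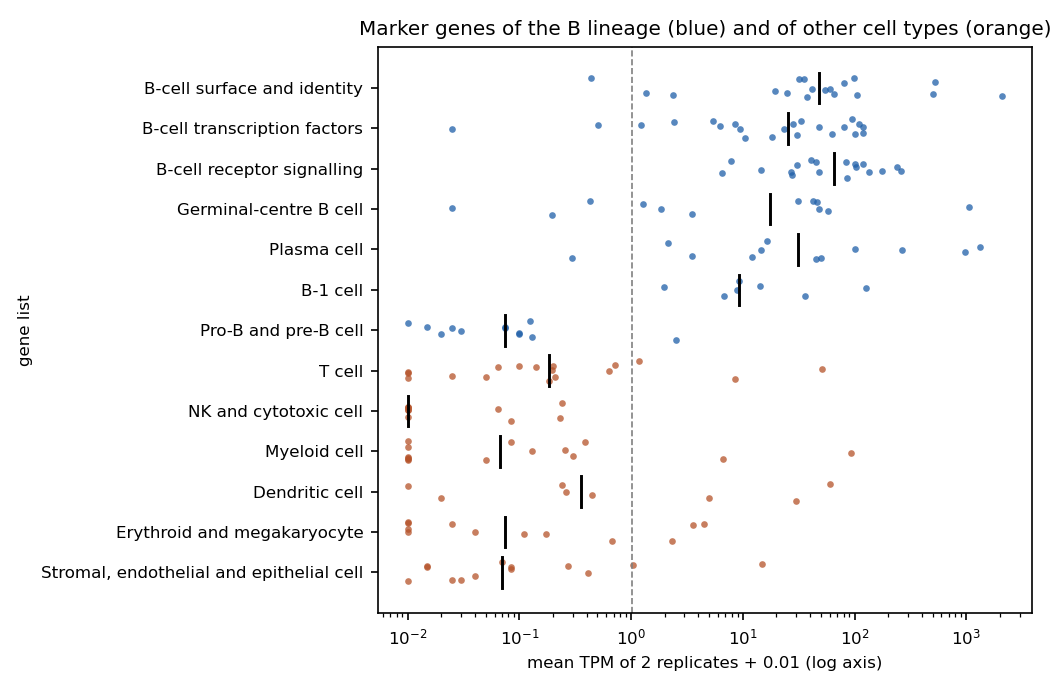
Mean TPM of the 2 replicates plus 0.01 on a log axis for each gene (points) of the lists for B-lineage stages (blue) and other cell types (orange), with the list median as a black bar and 1 TPM as a dashed line. The medians run from 9.33 to 66.1 TPM in the B-lineage lists other than pro-B and pre-B cells, and all of the lists for other cell types have medians below 1 TPM.

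The immunoglobulin heavy chain was carried by the IgA and IgM constant genes together. Igha (ENSMUSG00000095079.2, chromosome 12, 113254830 to 113260236, minus strand) stood at 2664 ± 203 TPM and made 63.4% ± 0.169 of the TPM on the 8 heavy-chain constant genes (SD, n = 2). Ighm (ENSMUSG00000076617.5, chromosome 12, 113418558 to 113422730, minus strand) stood at 1512 ± 127 TPM and made 36.0% ± 0.173. The ratio of Igha to Ighm was 1.76 ± 0.0132 by TPM and 1.61 ± 0.0285 by expected count. Ighg3 followed with 0.411% ± 0.0107, and Ighg2b, Ighg1, Ighe, Ighg2c and Ighd each held less than 0.1%, from Ighg2b at 2.40 ± 0.184 TPM to Ighd at 0.335 ± 0.0354 TPM. Counts on constant genes do not tell transcripts joined to a rearranged variable segment from germline transcripts of the same locus.

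The light-chain constant genes matched by symbol, a kappa and a lambda gene, were both expressed. Igkc, the kappa constant gene (ENSMUSG00000076609.1, chromosome 6, 70726435 to 70726966, plus strand), stood at 5042 ± 554 TPM and Iglc2, a lambda constant gene (ENSMUSG00000076937.2, chromosome 16, 19198396 to 19200351, minus strand), at 904 ± 77.5 TPM. Igkc made 84.8% ± 0.314 of the light-chain constant total by TPM and 59.4% ± 0.520 by expected count, since the Igkc transcript is shorter. A single segment dominated the heavy-chain and the kappa variable loci: Ighv1-53 held 99.7% ± 0.0930 of the counts on 175 heavy-chain variable genes, and Igkv10-96 held 99.4% ± 0.0942 of those on 103 kappa variable genes. The 3 lambda variable genes held only 32 and 25 counts, divided between Iglv3 (57.7% ± 2.39) and Iglv1 (42.3% ± 2.39), against 7683 and 6538 counts on Iglc2.

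**Figure D2:**
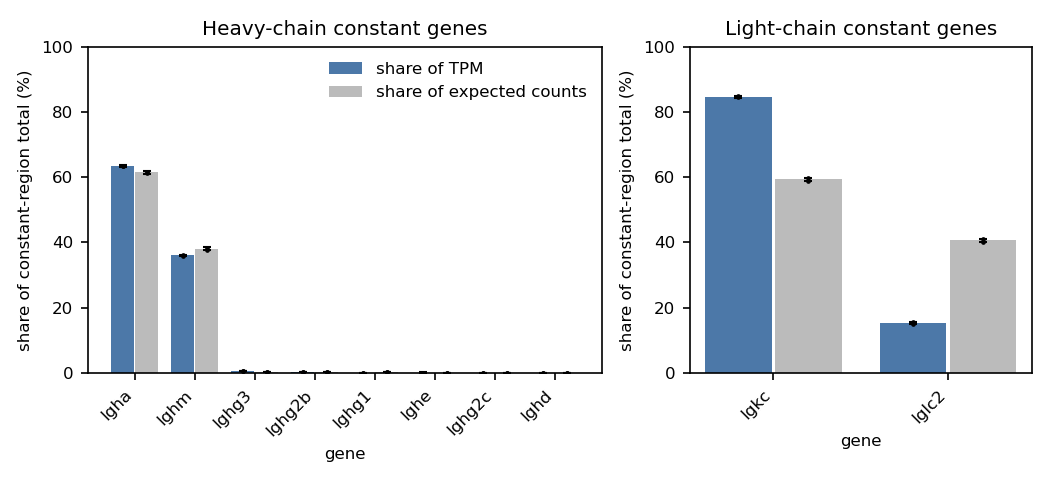
Share of each gene in the total of the heavy-chain (left) and light-chain (right) constant genes, in percent, by TPM (blue) and by expected count (grey), with bars at the mean, error bars at 1 SD and points for the 2 replicates. Igha and Ighm take 63.4% and 36.0% of the heavy-chain total by TPM, and the Igkc share moves from 84.8% by TPM to 59.4% by count.

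The genes listed for class switching and hypermutation were expressed broadly. All 27 genes reached 1 TPM, including the uracil glycosylase Ung at 35.6 ± 4.88 TPM and the endonuclease Apex1 at 334 ± 3.11 TPM, with Mdc1 lowest at 1.98 ± 0.389 TPM. Antigen presentation was expressed in full as well, with 12 of 12 MHC class II and 15 of 15 MHC class I genes passing. The invariant chain gene Cd74 stood at 2359 ± 165 TPM, its transactivator Ciita at 25.6 ± 0.290 TPM, and H2-Eb2 was lowest at 12.1 ± 0.629 TPM, while B2m, the class I light chain, stood at 1431 ± 99.4 TPM and H2-Q7 at 28.0 ± 5.68 TPM. H2-Ea-ps, annotated as a polymorphic pseudogene (ENSMUSG00000036322.10, chromosome 17, 34341959 to 34344645, minus strand), reached 875 ± 0.0849 TPM, which was 2.37 ± 0.0336 times H2-Aa and 2.03 ± 0.148 times its partner chain gene H2-Eb1. The near-identical genes H2-DMb1 and H2-DMb2, at 63.9 ± 11.5 and 129 ± 14.8 TPM, are uncertain because they can share reads. Whether the MHC alleles of this strain match those of the mm10 assembly was not examined. The levels and ratios of MHC genes, including H2-Ea-ps, may therefore depend on how reads of differing alleles were aligned.

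Of the costimulation and TNF-family genes, 10 of 14 passed. They were led by Tnfrsf13b, a receptor for the survival factors BAFF and APRIL, at 265 ± 8.32 TPM, and Cd70, the ligand of CD27, at 223 ± 33.3 TPM, with Cd40 at 159 ± 17.9 TPM and Cd86 at 148 ± 1.79 TPM. The homing list had 11 of 13 genes at 1 TPM or more, with Ccr7, which guides lymphocytes to T-cell zones, at 146 ± 14.6 TPM and Cxcr5, which guides B cells to follicles, at 62.4 ± 9.72 TPM. Among cytokine and TGF-beta receptor genes 14 of 15 passed, with Il5ra, the IL-5 receptor chain, at 78.6 ± 7.09 TPM, Tgfbr2 at 19.8 ± 0.587 TPM and Smad3 at 0.750 ± 0.594 TPM.

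All 12 NF-kappaB genes passed, led by Nfkb1 at 274 ± 12.2 TPM and the inhibitor gene Nfkbia at 86.8 ± 12.8 TPM, with Bcl3 lowest at 2.83 ± 0.509 TPM. Of the Toll-like receptor genes 11 of 13 passed, with Ly86, a partner of the receptor CD180, at 354 ± 35.2 TPM, Tlr4 at 18.5 ± 1.65 TPM and Tlr9, a receptor for unmethylated DNA, at 0.595 ± 0.262 TPM. The interferon-stimulated list split: Bst2 was high at 209 ± 7.31 TPM, but the list had 8 of 12 genes at 1 TPM or more and a median of 2.58 TPM, with Rsad2 at 0.0750 ± 0.0212 TPM. Of the apoptosis regulators 13 of 14 passed, with the survival gene Mcl1 at 168 ± 1.10 TPM, Bax at 124 ± 4.09 TPM, Bcl2 at 7.00 ± 0.474 TPM and Bcl2l2 at 0.310 ± 0.0990 TPM.

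The cells expressed the full proliferation list, 18 of 18 genes with a median of 182 TPM, from the replication clamp Pcna at 662 ± 38.6 TPM to the mitotic kinase Plk1 at 22.6 ± 0.969 TPM. Of 17 growth and tumour-suppressor genes 12 passed, with Cdk4 at 641 ± 36.8 TPM, Myc at 32.6 ± 6.07 TPM, Trp53, which encodes p53, at 15.6 ± 5.03 TPM and Ccnd1 at 0.0450 ± 0.0212 TPM. The neighbouring genes Cdkn2a and Cdkn2b, which encode inhibitors of the cyclin D kinases, had 0 counts in both libraries. A count of 0 allows up to 0.221 and 0.230 TPM for Cdkn2a (chromosome 4, 89274471 to 89294653) and up to 0.123 and 0.128 TPM for Cdkn2b (chromosome 4, 89306299 to 89311039). Mtap, a methionine-salvage gene next to them that was chosen after its value was seen, also had 0 counts (chromosome 4, 89137122 to 89181081).

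**Figure D3:**
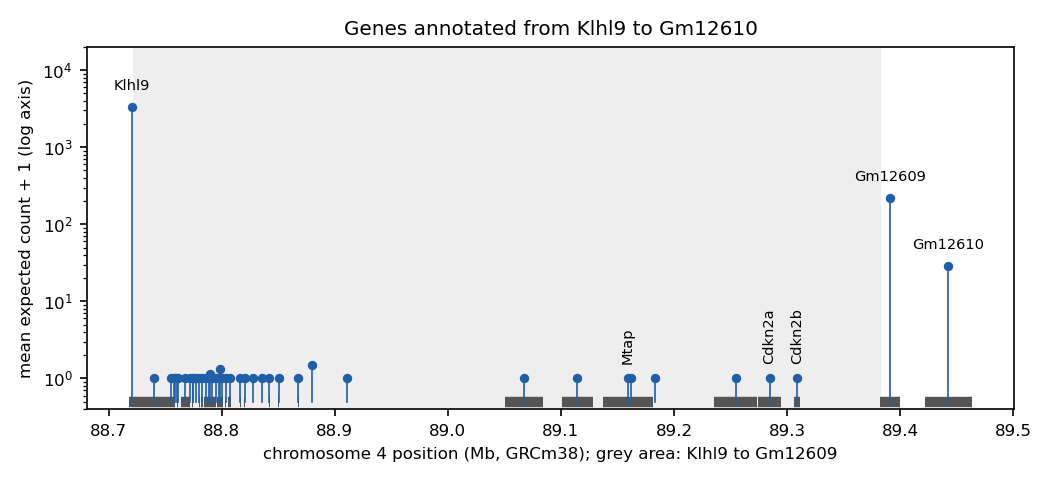
Mean expected count plus 1 (log axis) of each gene annotated on chromosome 4 around Cdkn2a and Cdkn2b, by position in GRCm38, with gene bodies as grey boxes and the area between the nearest genes with counts shaded. The 40 genes between Klhl9, with 3274 and 3338 counts, and Gm12609, with 244 and 187 counts, have at most 1 count in a library.

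Most genes of the metabolic and stress lists were expressed. Of 12 glycolysis and hypoxia genes 11 passed, with Pkm, a pyruvate kinase, at 1999 ± 151 TPM and the hypoxia-induced hydroxylase gene Egln3 at 0.050 ± 0.0424 TPM. All 11 cholesterol-synthesis genes passed, with Fdps, a farnesyl diphosphate synthase, highest at 390.2 ± 42.8 TPM. Of 12 amino-acid and endoplasmic-reticulum stress genes 11 passed, with the chaperone Hspa5 at 953 ± 74.8 TPM and the serine-synthesis enzymes Phgdh at 432 ± 27.2 and Psat1 at 409 ± 19.6 TPM, whereas Asns, the asparagine synthetase gene, held 1 count in each library. Of 14 immediate-early and heat-shock genes 9 passed, with Hsp90aa1 at 1186 ± 198 TPM, Junb at 148 ± 22.8 TPM, Fos at 0.365 ± 0.304 TPM and Hspa1a at 0 counts.

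The Y-linked genes were expressed although the labels give the sex of the line as female. All 4 Y-linked genes passed in both replicates: Eif2s3y, a translation initiation factor subunit, stood at 92.3 ± 12.9 TPM, the helicase gene Ddx3y at 55.0 ± 9.998 TPM, and the histone demethylase genes Uty and Kdm5d at 14.5 ± 2.30 and 12 ± 1.252 TPM. Relative to their X-linked copies, Ddx3y stood at 0.365 ± 0.0655 times Ddx3x, Eif2s3y at 0.444 ± 0.0649 times Eif2s3x, Kdm5d at 0.704 ± 0.0469 times Kdm5c and Uty at 1.13 ± 0.138 times Kdm6a. Xist, the RNA that coats the inactive X chromosome, held 0 counts in replicate 1, which allows up to 0.0238 TPM, and 2 counts in replicate 2. Tsix had 0 counts in both.

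**Figure D4:**
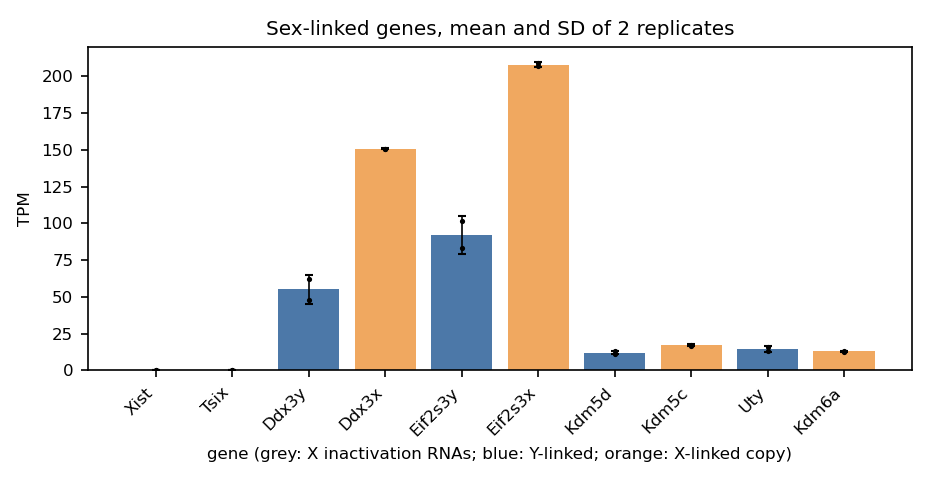
TPM of the X-inactivation RNAs Xist and Tsix, of 4 Y-linked genes (blue) and of their X-linked copies (orange), with bars at the mean, error bars at 1 SD and points for the 2 replicates. The Y-linked genes range from 12 to 92.3 TPM, while Xist is at 0.00500 TPM.

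The RNA classes bear on whether the libraries held RNA without poly(A) tails, since the labels name the assay as total RNA sequencing and also describe the RNA as poly(A)-selected and longer than 200 nt. Small RNA classes took 0.0477% ± 0.0254 of the expected counts, with 0.0657% in replicate 1 and 0.0298% in replicate 2. Replication-dependent histone genes, whose mRNAs end in a stem-loop in place of a poly(A) tail, took 0.0339% ± 0.00837. Of 64 histone genes 52 were tested for differences, and Hist1h2bg was highest at 113 ± 22.6 TPM, with levels of single histone genes uncertain because similar copies share reads. Of 8 RNAs without a canonical poly(A) tail 5 reached 1 TPM, with Rn7sk, the RNA of the 7SK particle, at 874 ± 543 TPM, Rpph1 at 459 ± 145 TPM, Malat1 at 164 ± 42.0 TPM and Neat1 at 7.54 ± 1.42 TPM. The 0 counts of Rnu11 and Rnu12, which are 134 and 151 nt long, have no bearing on poly(A) tails, since RNAs of that length fall below the size selection. Of 9 polyadenylated replacement histone genes 8 passed, with H2afz at 3569 ± 253 TPM and H1fx at 0 counts. Ribosomal-protein genes, 95 of 102 at 1 TPM or more with a median of 1428 TPM, took 7.50% ± 0.214 of the counts, mitochondrially encoded genes 2.06% ± 0.214, immunoglobulin segments 0.614% ± 0.0484 and pseudogenes 3.21% ± 0.0718. The mitochondrial list had 15 of 37 genes at 1 TPM or more, and its 22 tRNA genes, likewise shorter than the selected RNA, had 0 counts.

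The replicates were close across genes. Over 43346 genes the Pearson correlation of log2(TPM + 1) was 0.996 and the Spearman correlation of TPM 0.944, both across genes, which are not independent replicates. The median absolute log2 difference was 0.135 over the 11661 genes with a mean expected count of 20 or more. The robust SD per replicate was 0.22 log2 units for genes of 20 to 100 counts, 0.15 from 100 to 1000 counts, 0.11 from 1000 to 10000 counts and 0.12 above that. The counts were compared to see whether both replicates are the same library, which they are not: over 9859 genes with whole counts the chi-square statistic was 10.1 per degree of freedom, and 2940 genes lay outside the binomial counting error at a Benjamini-Hochberg threshold of 0.05 (1324 higher and 1616 lower in replicate 2), of which 144 differed over 1.5-fold. Separate biosamples ordinarily differ by more than counting error, so these numbers compare 2 libraries and measure no biological difference.

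More than 2-fold differences were few, 49 of 11661 genes, with 16 higher and 33 lower in replicate 2, and 28 of the 49 also differed over 2-fold by expected count. Of the 10 genes of 100 or more counts with the largest falls, 4 were lower in counts as in TPM without uncertain reads, among them Rn7sk at -1.36 on the log2 scale, Gm42418, a non-coding gene, at -1.28, and Hist2h2aa1, a histone H2A gene, at -1.27. Other genes differed mostly in TPM, with closer counts: Ccdc191 at -2.29 held 342 and 318 counts, the adaptor gene Lcp2 at -2.10 held 281 and 255, and Coq4, of coenzyme Q synthesis, at 0.90 held 566 and 505. Bckdhb, a subunit of branched-chain keto acid dehydrogenase, at 1.09, Slc25a53 at 0.86, Mesd at 0.83 and Ninl at 0.81 also differed less by count. Reads shared with similar or overlapping genes make the assignment uncertain for Gm12671 at -7.42, mt-Nd4l at -1.59, Rpl7a-ps11 at 0.90 and Moap1 at 1.05. The same holds for Gm7336 at 1.53, 2210418O10Rik at 2.40 and Gm2004 at 5.23. Rn7s1 and Rn7s2, at -1.29 each, held equal counts, 5518.5 each in replicate 1 and 2180.5 each in replicate 2. How shared reads divide between these 2 genes is uncertain, but both also fell by expected count (-1.28 each).

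Several gene groups moved together between the replicates. Of 34 lists with at least 3 tested genes, 10 had a median log2 difference outside the central 95% of 10000 random lists matched on expected count. Of these, 9 lay below and 1 above, where 1.7 would be outside for genes drawn at random. Genes of a list can share GC content or vary together, so that number sets no chance level for these lists. The calls describe these 2 libraries. The cholesterol-synthesis list fell by 0.40, with 11 of 11 genes lower in replicate 2, among them Insig1, a sensor of sterol levels, at -0.51. The glycolysis and hypoxia list fell by 0.23, with 11 of 11 genes lower by TPM. These ran from Ndrg1 at -1.22 and the mitophagy gene Bnip3 at -0.75 (-0.48 by expected count) to Pfkp at -0.062. Hk2, at -0.21 by TPM, stood at 0.042 by expected count. Replication-dependent histone genes fell by 0.46 with 50 of 52 lower, and RNAs without a canonical poly(A) tail fell by 0.53 with 4 of 5 lower, while Neat1 stood at 0.36. The mitochondrially encoded list fell by 0.26 with 14 of 15 lower and mt-Atp8 at 0.47 by TPM but -0.0073 by expected count.

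B-cell transcription factors fell by 0.19 with 16 of 21 genes lower, among them Irf4 at -0.24 and Spi1, which encodes PU.1, at -0.52 by TPM but only -0.16 by expected count, and homing and chemokine receptors fell by 0.20 with 8 of 11 lower, among them Cxcr5 at -0.32. Growth and tumour-suppressor genes fell by 0.12 with 9 of 12 lower and Trp53 at -0.65, a call that was lost at -0.039 with edgeR's TMM scaling, at -0.035 with median-of-ratios scaling and at -0.026 with spike-in scaling. Ribosomal-protein genes fell by 0.042 with 56 of 96 lower, and their median was 0.013 once GC content and length were corrected. The sex-linked list rose by 0.30 with 4 of 4 Y-linked genes higher in replicate 2, and stood at 0.15, inside the range of random lists, after the same correction. The other 24 lists lay inside that range, with medians from -0.14 for the heavy-chain constant genes to 0.080 for the interferon-stimulated genes, among them proliferation at 0.021, reference genes at -0.0041 and polyadenylated replacement histones at -0.01. Among these 24, NF-kappaB, at -0.091, and MHC class II, at -0.086, fell below the range when expected counts replaced TPM (-0.19 and -0.11 with TMM scaling), and NF-kappaB also after the correction for GC content and length (-0.13). Single reference genes still differed, with Gapdh and Polr2a both at -0.50. Across 11597 genes the log2 difference fell with GC content (Spearman rho = -0.342 across genes), from a median of 0.13 in the lowest eighth of genes by GC content to -0.11 in the highest.

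**Figure D5:**
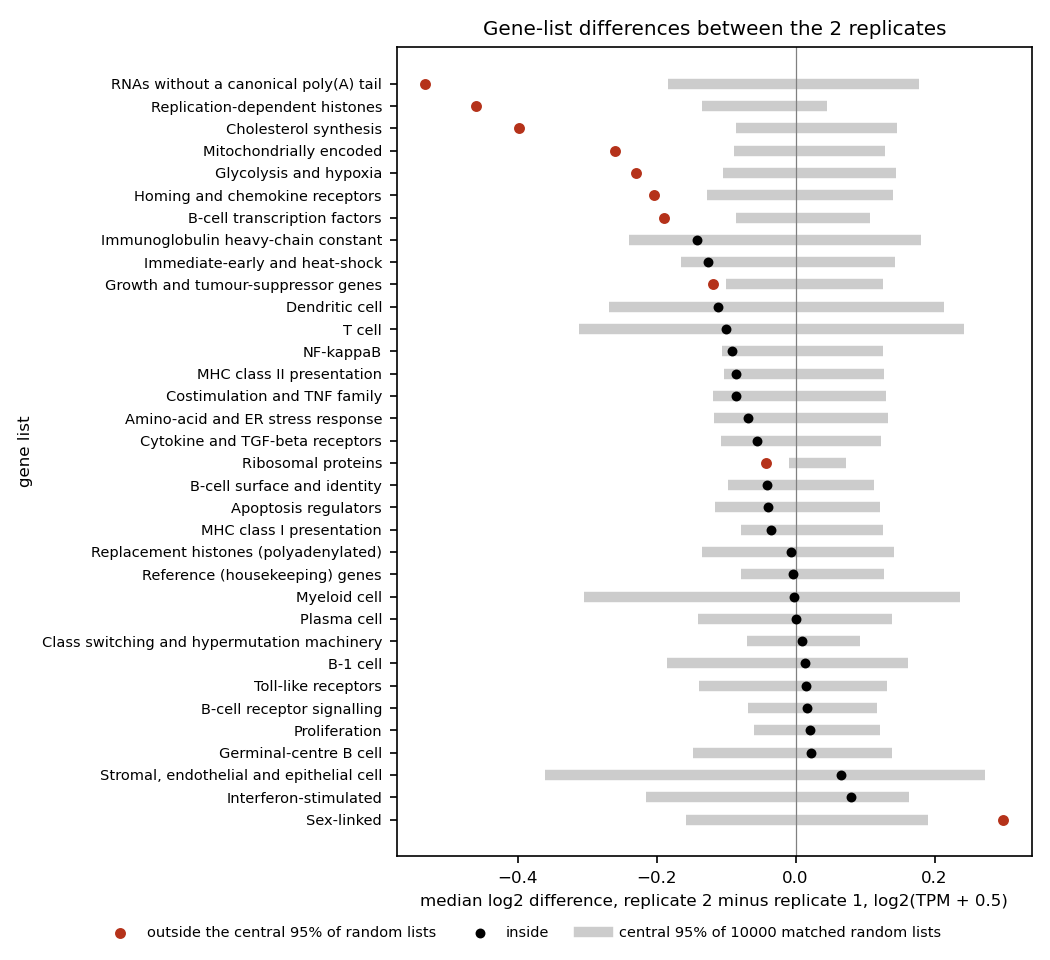
Median log2 difference of TPM (replicate 2 minus replicate 1) of 34 gene lists (points), with the central 95% of 10000 matched random lists as grey bars and the 10 lists outside it in red. The histone, cholesterol-synthesis and glycolysis lists lie at -0.46, -0.40 and -0.23, and the sex-linked list lies above its range at 0.30.

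The added ERCC spike-in RNAs, which carry no biology of the cells, took 0.289% ± 0.0446 of the expected counts and were 0.803 times as abundant in replicate 2. Of 96 spike-ins 70 were detected, with a median log2 difference of -0.34, below the central 95% of matched endogenous lists, and 52 of 70 were lower in replicate 2. The SD of their log2 differences was 0.46, at percentile 82.5 of endogenous genes in matched count bins. For the 38 spike-ins with a mean of 20 or more counts the SD was 0.26, at percentile 50.3. For the 28 with a mean of 100 or more counts it was 0.19, at percentile 16.6. Whether the spike-ins varied more or less than endogenous genes thus depended on the count minimum. Scaling to the spike-ins moved the median of all genes by 0.29, and differences under that scaling are given relative to that median.

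At the level of transcripts, 6510 of 7033 genes had the same most abundant transcript in both replicates, 92.6% (Wilson 95% interval 91.9% to 93.2%). The most abundant transcript took a median of 76.2% and 75.1% of its gene. For Ighm, the shorter transcript Ighm-201, which ends at the secreted terminus, made 64.4% ± 0.156 and Ighm-202, which extends downstream over the membrane exons, 35.6% ± 0.156 (SD, n = 2). For Igha, examined after its level was seen, the shorter Igha-201 made 75.6% ± 0.841 and the downstream-extended Igha-202 24.4% ± 0.841. The leading transcript made 97.9% ± 0.0990 of Pkm, 93.4% ± 2.38 of Ikzf1, 90.6% ± 2.60 of Xbp1, 60.4% ± 1.16 of Irf4 and 72.7% ± 0.184 of Bcl2l1. For Ptprc, which encodes CD45, the 2 replicates had different leading transcripts, Ptprc-207 with 30.6% ± 5.02 and Ptprc-203 with 25.3% ± 6.64 over both. A single transcript took 100% of Cd79a, and Cd22 was led by a short non-coding transcript, Cd22-206, with 23.8% ± 11. That lead by TPM rests on its length of 358 nt, as Cd22-206 held only 31.2 and 52.9 of the 2146 and 1962 counts of Cd22. Among the other genes fixed for this comparison the leading transcript took 38% ± 0.0566 in Foxp1, 82.0% ± 7.21 in Pax5 and 99.7% ± 0.240 in Mcl1.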

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

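The phiX174 genome, a bacteriophage sequence used as a control on sequencing instruments and present among the quantified sequences, belongs to no gene list and enters only the shares of RNA classes. It held 11584 expected counts in replicate 1 and 8045 in replicate 2, far above the 3 counts that a count of 0 allows. No explanation was tested.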

How the results depend on the processing

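The settings added after the data were seen are median-of-ratios scaling of the lists, the removal of features of effective length under 100 nt, the correction for GC content and length, the spike-in minimum of 20 counts and their robust SD. No paired analysis was possible because the design has only 1 group, so no groups share replicate numbers. Results that need both replicates (correlation, differences and top transcripts) could not be computed with a replicate left out. The number of detected genes stayed within 1.5 times under every setting, from 8513 at 5 TPM to 12782 by posterior mean TPM. The Pearson correlation moved to 0.992 with a pseudocount of 0.1, 0.994 for genes with a mean count of 20 or more and 0.980 by posterior mean TPM. Over 2-fold differences numbered 285 without a filter (128 higher and 157 lower in replicate 2), 22 at a mean count of 100 or more, 94 with a pseudocount of 0.1 and 26 with a pseudocount of 2. The split of higher to lower genes, 16 to 33 in the main setting, was 10 to 24 with TMM, 10 to 23 with median-of-ratios, 9 to 28 with spike-in scaling and 8 to 42 by posterior mean TPM. At 5 TPM, expressed members fell to 0 for pro-B and pre-B cells, 7 of other cell types in all, 0 erythroid, 3 interferon-stimulated and 5 immediate-early genes. At 0.5 TPM they were 5 T-cell and 2 stromal genes, and the stromal list gave from 1 to 2 genes with 1 replicate left out. By expected count, Igha took 61.5% and Ighm 38.1% of the heavy-chain and Igkc 59.4% of the light-chain constant total. MHC class II passed below the random lists with TMM (-0.11), spike-in (-0.097) and median-of-ratios scaling (-0.11), and NF-kappaB with TMM (-0.19), spike-in (-0.18), median-of-ratios scaling (-0.19) and the GC correction (-0.13). Growth and tumour-suppressor genes returned inside with TMM (-0.039), spike-in (-0.026), median-of-ratios scaling (-0.035) and no filter (-0.033), the mitochondrial list with no filter (0, since its 22 tRNA genes at 0 counts enter), and the sex-linked list with the GC correction (0.15). The ribosomal-protein median reversed to 0.013 with the GC correction. Of 303 list values under other settings, 20 changed sign without being called either way. Shares by TPM in place of counts were 59.2% for other protein-coding genes, 16.7% for ribosomal-protein genes, 10.3% for mitochondrial genes, 9.58% for pseudogenes, 1.82% for immunoglobulin segments, 0.949% for long non-coding genes, 0.689% for small RNA, 0.495% for spike-ins, 0.133% for genes without a symbol, 0.121% for histones, 0.00925% for phiX174 and 15.7% for the 10 highest genes, since TPM divides by length. The same leading transcript was found in 90.5% of genes from 20 counts, 94.6% from 1000 counts and 98.1% where it took 60% or more in 1 replicate. By posterior mean TPM, Xist was at 0.50 and Tsix at 0.010. Tsix had 0 counts in both libraries, so this measure can lie above 0 without reads. Among named genes Coq4 reversed to -0.10 with TMM, -0.097 with median-of-ratios and -0.092 with spike-in scaling, and Gm7336 to -0.014 by posterior mean TPM. Of the other values of named genes, 504 stayed, 45 moved and 20 were weaker, most of them by posterior mean TPM. A level or share counted as moved when it lay 1 SD or more from the mean. With 2 replicates, each replicate alone always lies within 1 SD of their mean. Levels and shares with 1 replicate left out therefore could not move, and many of the 504 values were fixed in advance and show no robustness. Where no reason is given, the cause was not tested. Depth limits genes of 20 to 100 counts, whose counting error alone is 0.21 log2 units per replicate.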

Other observations

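Several secreted and surface genes outside the fixed lists, chosen after their values were seen, were among the most abundant in CH12.LX. Ccl22, a chemokine that attracts CCR4-bearing T cells, stood at 960.0 ± 159 TPM, and Il10, an anti-inflammatory cytokine, at 716 ± 32.6 TPM (n = 2). Cd52, a small lymphocyte surface antigen, reached 3742 ± 625 TPM, the transferrin receptor gene Tfrc 673 ± 41.4 TPM, the fatty-acid receptor gene Cd36 449 ± 34.1 TPM and the lymphoid antigen genes Ly6d and Ly6k 367 ± 80.7 and 362 ± 36.4 TPM. Of the survival genes related to Bcl2, Bcl2a1b stood at 672 ± 35.1 TPM and Bcl2a1d at 387 ± 16.9 TPM, a near-identical pair that can share reads, against 7.00 ± 0.474 TPM for Bcl2.

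Other genes chosen after their values were seen were Odc1, the ornithine decarboxylase gene, at 1388 ± 10.1 TPM and Cth, which makes cysteine from cystathionine, at 461 ± 35.8 TPM. Asns, the asparagine synthetase gene on chromosome 6 (7675169 to 7693254), stood at 0.030 TPM with 1 count in each library. Genes of chromosome 6 chosen for comparison after the Asns value was seen were expressed: Rpa3 at 207 ± 5.52 TPM, Mios at 18.7 ± 0.686 TPM and C1galt1 at 14 ± 2.14 TPM.

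The tests of the Y-linked genes, of GC content and length, of the proliferation list and of genes of histone length were chosen after the results were seen, whereas the small nuclear and nucleolar RNAs and both second lists were tested with predictions written before. No design group gives a biological contrast, so no biological explanation was tested against a group.

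The first pattern is the expression of Y-linked genes, with Xist near 0, in a line labelled female. Reads shared with the X-linked copies were tested by the posterior SD of the Y-linked counts, which was 0% of the count in all 4 genes and both libraries, against over 10% needed. No other explanation was tested, and whether the line, the culture or the sex entry departs from the donor stays open, since no DNA was analysed here.

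The second pattern is the fall of histone genes and RNAs without poly(A) tails in replicate 2. The proliferation list did not fall with the histone genes: its median was 0.021, where fewer cells in S phase was taken to predict below -0.1. That bound was set with the value known, and the list mixes replication genes such as Pcna with mitotic genes such as Plk1. It therefore cannot exclude fewer cells in S phase. Loss of short RNAs as the whole cause was argued against by other protein-coding genes, whose medians were -0.016 for 2568 genes of 312 to 1623 nt, run first, and -0.068 for 300 genes of 423 to 745 nt, the middle lengths of the histone genes, chosen after the first value was seen; both lay below the range of random lists, so a small part of the fall is not excluded, but above the bound of -0.15. Less carry-over of RNA without poly(A) tails may account for the pattern but cannot be told apart from other explanations. The small nuclear, nucleolar and Cajal-body RNAs outside the fixed list had a median of -0.23 over only 4 genes. That median lay at percentile 10.5 of random lists and between the bounds of -0.1 and -0.3 set before. Outside that prediction, Rn7s1 and Rn7s2 were at -1.29 each. Small RNA classes held 0.454 times the share of counts in replicate 2. Rn7s1, Rn7s2 and Rn7sk held most of the counts of these classes in both libraries. The ratio therefore mostly repeats the fall of those genes and does not show a fall across the classes. The spike-ins, with a median of -0.34, and the mitochondrially encoded genes, at -0.26, were lower in replicate 2 as well. Whether these falls share a cause with the pattern was not tested, and they do not tell its explanations apart.

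The third pattern is the fall of cholesterol and glycolysis genes in replicate 2. GC content and transcript length as the whole cause was argued against by both lists after correction, at -0.34 for cholesterol and -0.17 for glycolysis and hypoxia, each below the range of random lists. Second lists, written before their values were seen, also fell: a sterol list that includes fatty-acid genes had a median of -0.32 with 16 of 17 genes lower, and a glycolysis and hypoxia list had -0.21 with 16 of 21 lower (-0.37 and -0.10 after correction, still below the range). Not every glycolysis gene fell: Tpi1 stood at 0.11, Hk1 at 0.086 and Pgam1 at -0.032, and Pgk1 of the reference list at -0.012. The hypothesis that most listed sterol, glycolysis and hypoxia genes were expressed at a lower level in the culture of replicate 2 may hold. Culture density, medium and day were not analysed here, and 1 library on each side cannot separate culture from library preparation.

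A stretch without expression surrounds Cdkn2a, and it was bounded by its nearest genes with counts after the values were seen. Between Klhl9, at 40.9 ± 1.75 TPM, and Gm12609, at 27.1 ± 4.31 TPM, on chromosome 4 (88722466 to 89381956, GRCm38, 659 kb), 40 genes are annotated, 24 of them protein-coding, and the highest count of a gene in a library was 1. Most of the coding genes are interferon genes, which unstimulated cells seldom express, but Mtap is a housekeeping enzyme gene and had 0 counts, which allows up to 0.0986 and 0.103 TPM. No explanation was tested, and no DNA was analysed here.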
